A study of Homo sapiens with 5 samples.

How the data were processed

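Mitochondria were isolated from HEK293T cells, a human embryonic kidney line, either wild type or with the FASTKD5 gene knocked out. Per the labels' protocols, cells grew in suspension for 4 days, and 3 mg of fresh mitochondria were incubated with 1% dimethyl sulfate (DMS) for 5 min at 37 °C. DMS methylates accessible adenines and cytosines, and a suitable reverse transcriptase writes those methylations as mutations. The labels give 5 libraries: 2 of DMS-treated wild type, 2 of DMS-treated knockout and 1 of untreated wild type. Per the labels' protocols, 1 µg of RNA was fragmented at 95 °C for 2 min, libraries were selected at about 300 nt, and paired reads of 150 nt were planned at 250M per sample. The extraction protocol names Induro as the reverse transcriptase, whereas the series' design text names TGIRT. Which enzyme made these libraries was not settled here.

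Cutadapt and Bowtie2 are named without versions, with the builds GRCh38 and hg38, per the submitters' processing notes. The design text names SEISMIC-RNA and RNAstructure for structure models. How the deposited values were made, which reads were kept and whether the 2 replicates of a genotype were pooled are not given in the sources used here. The deposited files were 4 tables, 1 for each genotype and strand, and each gave 1 value for each of the 16569 positions of the mitochondrial genome, under a column that the authors headed as normalized DMS, per the file headers.

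What the values hold was examined before any comparison was computed. Neighbouring values differed by a median of 0.742% in the wild-type plus table and 0.790% in the knockout plus table, at positions with a value of 1 or more, and values dropped to near 0 across most plus-strand tRNAs, though not across tRNAL1. The deposited values were therefore treated as the authors' normalized read coverage, a signal per strand, and not as a DMS reactivity for each base. Plus tables held values of 0 or above, and minus tables held values of 0 or below, whose sign was turned here. The signed values of both tables of a genotype averaged 1.00 per position, so the authors' coverage signal was scaled within each genotype. The size of that factor and the read depth are unknown, and values carried 3 decimals. The tables had no replicate columns, so no spread between replicates, interval or test between genotypes could be computed, and no p-value was made from positions or genes. Every difference between the genotypes is a difference between the authors' deposited values and has no replicate check.

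Before the data were examined, the comparisons, the transcript lists, the junction classes and most alternative settings were fixed for DMS reactivities at adenines and cytosines. Because the values were coverage, the same comparisons were run on every position. Coverage has no base preference, and no mitochondrial sequence was used here, so the planned splits by base and by codon position, the comparison at naturally modified bases and the RNA folds were not run. The untreated wild-type library was not analysed here, since no table was named for it. The FASTKD5 gene is nuclear, and its own level was therefore not measured by these mitochondrial tables.

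The deposited tables divide the genome into 41 segments, of which 35 were matched to 37 genes of RefSeq GRCh38.p14. Starts were identical for 30 of them and ends for 28, and the largest differences were 3 nt and 4 nt. ATP8 with ATP6 and ND4L with ND4 form single segments, so there were 11 mRNA segments. Coordinates are those of the tables, on the mitochondrial genome (MT), counted from 1. For each segment and strand, the mean of each genotype, the log2 ratio of knockout over wild type and Pearson's r across positions were computed. No ratio was given for a segment where either mean lay below 0.01, and windows next to junctions had no such floor. For a strand, a position counted as different when the deposited values differed by more than 0.2.

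At a junction, the outside share was defined here as the mean coverage of the 50 nt on the precursor side over the mean of the first 50 nt inside the transcript, as a percent. At ATP6/COX3 the outside 50 nt are the end of ATP6, so ATP6 RNA cut from COX3 counts there as well. At tRNA-flanked ends the outside 50 nt are tRNA. A junction was measurable when the inside mean was at least 0.05. Outside ratios were placed among those of 10000 random 50 nt windows of the same strand, as a description of these tables. Junctions not flanked by a same-strand tRNA were set beside tRNA-flanked 5' ends. The difference of the class medians was ranked among all ways of splitting the measurable junctions into classes of these sizes. A step was the largest increase between neighbouring positions within 10 nt of the junction, into the transcript, and is given as the ratio of both values. Stretches were called when at least 50 nt in a row differed at least 2-fold, with a value of at least 0.05 in the higher genotype.

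The rule for naming took any gene of the segment table, the 4 junctions without a tRNA, the 10 segments with the largest and smallest differences or correlations, and the 10 positions with the largest rise and fall on each strand. Sites and stretches outside that rule were chosen after their values were seen. Alternatives covered the scaling between genotypes, values of 0, capping at the 99th percentile, pseudocounts of 0.01 and 0.1, the windows and the thresholds. With a pseudocount, segment and window ratios were made from averaged log2 values in place of averaged values, so those settings changed the average as well. Scaling by the unsigned coverage of both strands, scaling by coverage outside COX1, moving junctions to the wild-type step, leaving out the ND6 3' end, leaving COX1 out of the transcript list, and counting stretches and antisense segments under each scaling were added after the values had been seen. The calculation of segment and window ratios was tested on simulated tables with 13 known values, and the largest error was 0.0083 on the log2 scale. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.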

Results

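RNA of isolated HEK293T mitochondria was read in wild-type cells and in cells without FASTKD5, a mitochondrial RNA-binding protein of the FAST kinase domain family. The series asks how FASTKD5 acts on precursor RNAs at transcript ends that no tRNA marks. Human mitochondrial DNA is transcribed from both strands into long precursors, and most mRNAs are released when RNase P and ELAC2 excise the tRNAs between them. The 5' end of COX1, the border of ATP6 and COX3, the border of ND5 and CYTB and the 3' end of ND6 lack such a same-strand tRNA. Of the 5 libraries, 2 were DMS-treated wild type, 2 were DMS-treated knockout and 1 was untreated wild type, which was not analysed here. The authors' deposited values were 1 normalized coverage per genotype, strand and position, without replicate columns and with unknown depth, so every difference below lacks a replicate check. Mean coverage of the plus strand, which reads as most mRNAs, was 1.61 in wild type and 1.65 in the knockout, and that of the minus strand was 0.615 and 0.653. Because signed values of both strands average 1.00 in each genotype, both strand means must differ by the same amount. They are therefore not separate results.

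Coverage just upstream of COX1, COX3 and CYTB was higher in the knockout than in the wild type. COX1 and COX3 encode core subunits of cytochrome c oxidase, and CYTB encodes cytochrome b of complex III. In the 50 nt before COX1 (MT, 5852 to 5901), plus-strand coverage was 0.356 in wild type and 2.90 in the knockout, 8.12-fold higher. The 50 nt before COX3, which are the end of ATP6 (MT, 9158 to 9207), had 1.01 and 5.25, 5.22-fold higher. Before CYTB (MT, 14697 to 14746), coverage was 0.025 and 0.671, 26.9-fold higher. These ratios lay at percentiles 98.8, 96.7 and 99.8 of random windows of the plus strand. Those windows were drawn from the whole strand, these sites included, so the percentiles partly reflect how long the higher stretches are.

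Inside the transcripts the 3 sites differed from one another. The first 50 nt of COX1 had 5.45 in wild type and 5.25 in the knockout, so the outside share was 6.54% against 55.2%, a log2 difference of 3.08. The first 50 nt of CYTB were themselves 3.63-fold higher in the knockout (0.274 against 0.995), and the outside share was 9.11% against 67.4%, a log2 difference of 2.89. The first 50 nt of COX3 were 2.67-fold higher (1.73 against 4.62), and the outside share went from 58.1% to 114%, a log2 difference of 0.97. With 0.1 added to every value and log2 values averaged in place of the values, the log2 difference at CYTB was 1.02. Wild-type coverage there was low, and the parts of both changes in that shift were not told apart.

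The wild-type tables had a sharp step at each of these 3 sites that was nearly absent from the knockout tables. At COX1, wild-type coverage went from 0.762 to 4.30 after position 5904, a 5.64-fold step, and the knockout went from 4.20 to 4.44 there, 1.06-fold. At CYTB, the wild-type step after position 14749 was 3.78-fold, from 0.041 to 0.155, and the knockout step was 1.05-fold, from 0.751 to 0.785. At COX3, wild-type coverage declined along the end of ATP6 and then went from 0.853 to 1.40 after position 9209, 1.65-fold. Knockout coverage there went from 5.14 to 4.91, a ratio of 0.954. Across the window around the ATP6/COX3 border the profiles of the 2 genotypes ran in opposite directions (Pearson r = -0.79 across positions, which are not independent).

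**Figure D1:**
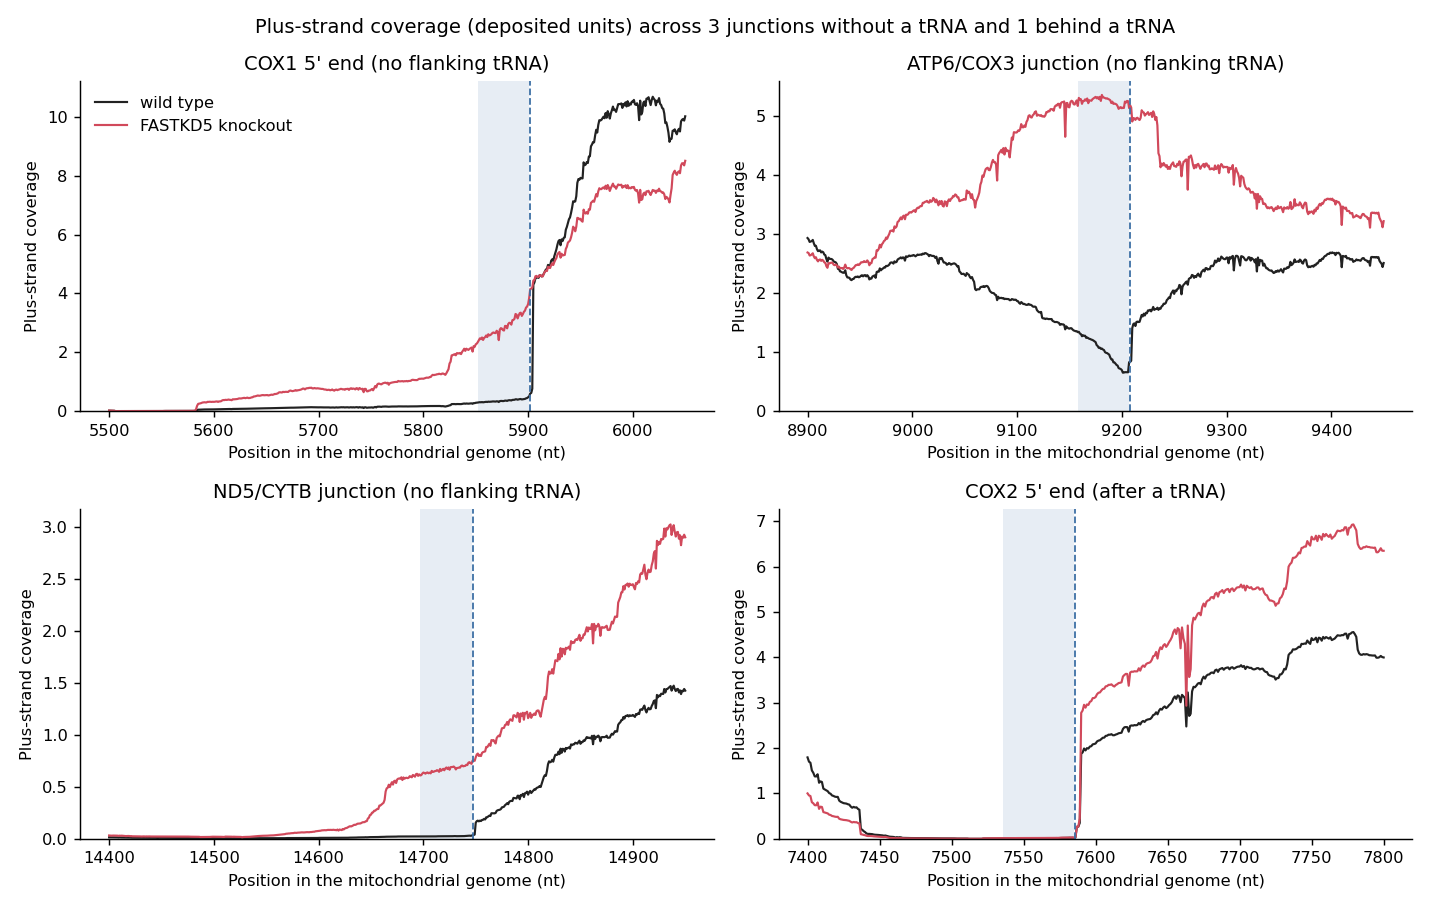
Plus-strand normalized coverage (deposited units, y axis) against position in the mitochondrial genome (nt, x axis) in wild type (black) and FASTKD5 knockout (red), with the junction as a dashed line and the 50 nt outside it shaded. The wild-type steps of 5.64-fold at COX1, 1.65-fold at COX3 and 3.78-fold at CYTB are 1.06-fold, 0.954-fold and 1.05-fold in the knockout, whereas the COX2 5' end after a tRNA has a step in both.

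The annotated ND6 3' end, which also lacks a flanking tRNA, had no sharp step in wild type that could be lost. ND6, a complex I subunit, is the only mRNA of the minus-strand tables. Coverage of the 50 nt beyond its annotated end (MT, 14099 to 14148) was 0.816 in wild type and 0.914 in the knockout, and the last 50 nt inside had 0.976 and 1.12. The outside share was 83.6% and 81.5%, a log2 difference of -0.04. The largest step within 10 nt of that end was 1.06-fold in wild type and 1.05-fold in the knockout. Wild-type minus-strand coverage thus ran on past the annotated end, and was 0.016 at positions 13591 to 13890. Where this RNA ends was not measured, so the site could hardly show the pattern of the other 3 and does not speak against it.

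The 5' ends that follow a tRNA kept low outside shares in both genotypes, apart from ND1. At COX2 the share was 0.681% in wild type and 0.607% in the knockout, with steps of 5.35-fold and 6.17-fold after position 7589. At the ATP8/6 5' end it was 1.31% and 1.90%, and at ND4L/4 it was 1.01% and 1.499%. ND2, ND3 and ND5 had 4.58%, 4.75% and 2.51% in wild type and 6.63%, 6.78% and 2.69% in the knockout. ND1 had the highest share of this class, 30.3% in wild type and 25.6% in the knockout. The log2 differences of these 7 ends ran from -0.24 to 0.57, and the signs at ND2 and ND5 turned when a pseudocount of 0.1 was added. Quantile normalization raised ND3 to 0.88, and windows of 100 nt raised the ATP8/6 5' end to 0.78. The 5' ends of RNR1 and RNR2, the rRNA genes, had too little coverage to be measured.

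The median log2 difference of the outside share was 1.93 over the 4 junctions without a tRNA and 0.51 over the 7 tRNA-flanked ends. The class difference of 1.41 was reached or exceeded by 14 of the 330 ways of choosing 4 of these junctions, and the highest other split gave 1.83. Without the ND6 3' end, an alternative chosen after its value was seen, the difference was 2.38, and 4 of 120 splits were as large. These counts describe 1 pair of genotypes and are no test between them. The outside windows also differ in kind, since that at ATP6/COX3 is the end of an mRNA and those of the tRNA-flanked class are tRNA. The ND6 3' end entered the median of the 4 junctions although it had no wild-type step and could hardly show a difference.

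**Figure D2:**
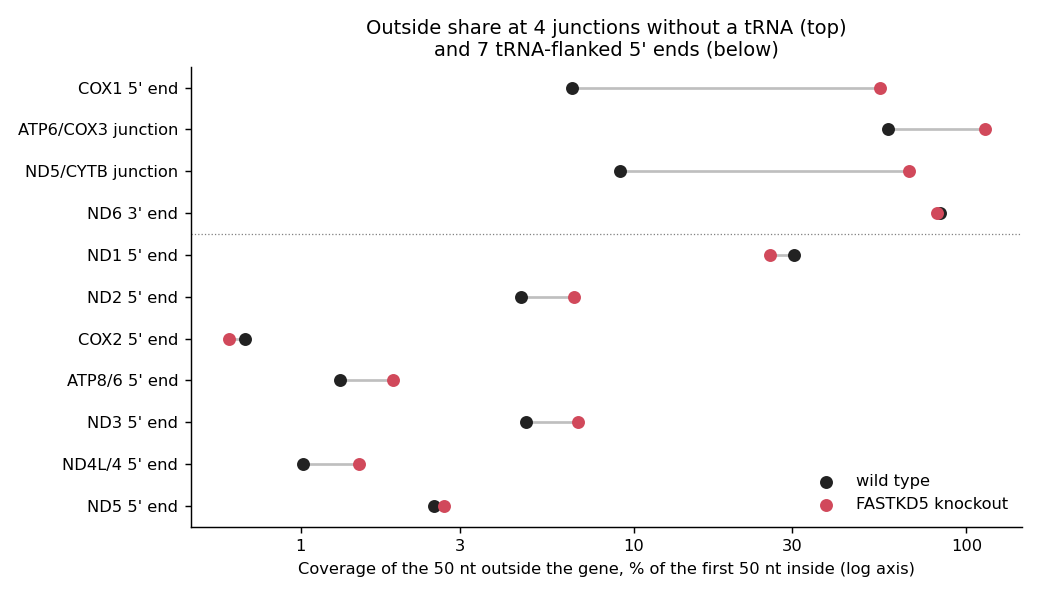
Coverage of the 50 nt outside each transcript end as a percent of the first 50 nt inside (x axis, log scale), with 1 row per junction, in wild type (black points) and FASTKD5 knockout (red points). COX1 moves from 6.54% to 55.2% and ND5/CYTB from 9.11% to 67.4%, whereas the ND6 3' end and the 7 tRNA-flanked ends lie close together in both.

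Upstream of COX1 the higher knockout coverage began at the end of the preceding plus-strand tRNA. It formed a stretch of 322 nt (MT, 5583 to 5904), with a mean of 0.171 in wild type and 1.205 in the knockout, 7.03-fold higher. The last 10 nt of tRNAW, the tRNA for tryptophan, had 0.0056 in wild type and 0.0061 in the knockout. The first 10 nt opposite tRNAA, which is read from the minus strand, had 0.055 and 0.296. Plus-strand coverage opposite the minus-strand tRNAs A, N, C and Y was higher by log2 ratios of 2.47, 2.56, 2.76 and 3.03, and it was higher under every setting tried. Quantile normalization lowered A, C and Y to 1.75, 1.83 and 2.41, and a pseudocount of 0.1 lowered A and N to 1.54 and 1.88.

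Between ND5 and CYTB, knockout coverage was low in the middle and built up towards CYTB. Opposite ND6, the plus-strand mean of 50 nt windows was lowest in wild type at 0.0051 (MT, 14499 to 14548) and lowest in the knockout at 0.020 (MT, 14449 to 14498). It was 1.77-fold higher in the knockout next to ND5, 2.43-fold opposite the middle of ND6 (MT, 14399 to 14448) and 24.0-fold at positions 14649 to 14698. Plus-strand coverage opposite tRNAE, which lies just before CYTB, was 0.024 in wild type and 0.646 in the knockout (log2 4.75, or 4.04 with quantile normalization and 2.59 with a pseudocount of 0.1). The end of ATP6 and the start of COX3 formed 1 stretch of 181 nt (MT, 9074 to 9254) with 1.51 in wild type and 4.90 in the knockout. As deposited, the plus strand had 7 such stretches with at least 2-fold higher knockout coverage, 1558 nt in all, and none with at least 2-fold lower coverage. The other 5 lay within the ND6 segment or at and within CYTB. Scaling by table medians, quantiles or coverage outside COX1 left 3 higher stretches, which lay at COX1, at ATP6/COX3 and at CYTB, and gave 2 lower ones, both starting in COX1, or 1 in COX1 and 1 in ND3 with quantiles.

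Among the mRNAs, COX1 was lower in the knockout tables, while CYTB, COX2 and ND5 were higher, under every scaling tried. COX1 coverage was 8.11 in wild type and 5.42 in the knockout (log2 -0.58). CYTB had 0.985 and 2.00 (log2 1.03), COX2, another cytochrome c oxidase subunit, had 3.47 and 5.26 (log2 0.60), and ND5, a complex I subunit, had 1.09 and 1.59 (log2 0.55). COX1 made up 46.5% of sense mRNA coverage in wild type and 30.8% in the knockout. CYTB made up 4.17% and 8.41%, COX2 8.82% and 13.2%, and ND5 7.30% and 10.6%.

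For the remaining mRNAs the direction or size often depended on the scaling. ND3 was lower in the knockout (log2 -0.20, or -0.81 with quantile normalization) and ND4L/4 was nearly equal (log2 -0.02), both below 0 under every scaling. ND2 was higher (log2 0.40) but had -0.025 with quantile normalization, and COX3 was higher (log2 0.38) but had -0.013 when scaled by coverage outside COX1. ND1, ATP8/6 and ND6 had 0.19, 0.20 and 0.28 as deposited, and all 3 were below 0 when scaled by table medians, by quantiles or by coverage outside COX1. As deposited, 8 of the 11 mRNA segments were higher in the knockout with a median log2 of 0.28, and 5 or 4 were higher under those 3 scalings. Scaling by table medians shifted log2 ratios by -0.37 on the plus strand and by -0.44 on the minus strand, and scaling by coverage outside COX1 shifted them by -0.39.

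**Figure D3:**
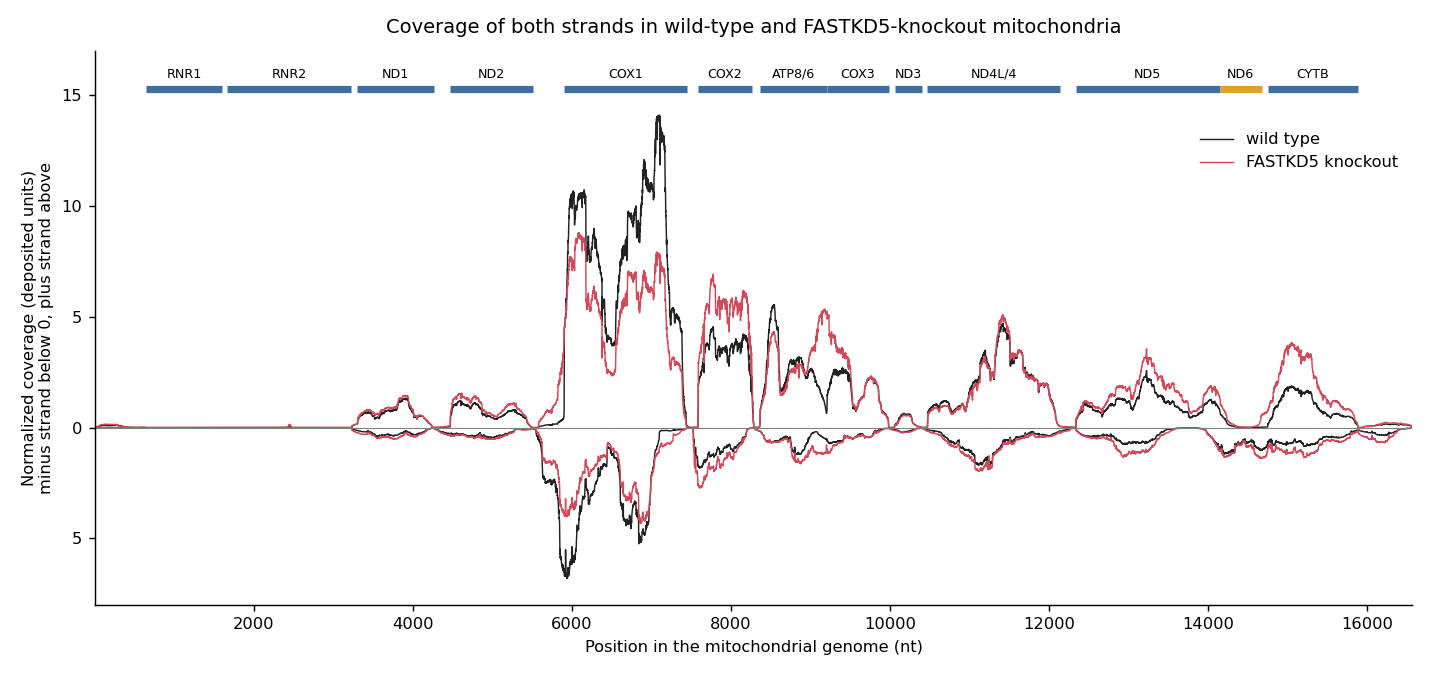
Normalized coverage (deposited units, y axis) along the mitochondrial genome (nt, x axis) in wild type (black) and FASTKD5 knockout (red), with the plus strand above 0 and the minus strand drawn below 0, and bars for rRNA and mRNA segments of the plus (blue) and minus strand (orange). COX1 reaches 14.1 in wild type and stays lower in the knockout, while COX2 and CYTB are higher in the knockout.

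By respiratory complex, the directions were mixed. Of the 6 complex I segments, 4 were higher and 2 lower in the knockout, with a median log2 of 0.23 that lay below 0 under scaling by medians, quantiles or coverage outside COX1. Complex III was CYTB alone (log2 1.03). In complex IV, COX2 and COX3 were higher and COX1 was lower, with COX3 turning under scaling by coverage outside COX1. Complex V was the joint ATP8/6 segment (log2 0.20), which turned under 3 scalings. The 10 segments other than ND6, whose mRNAs the LRPPRC-SLIRP complex is known to stabilise, had 7 higher and 3 lower, with a median of 0.29 that also turned under those 3 scalings. The 5 segments next to a junction without a tRNA (COX1, ATP8/6, COX3, ND5 and CYTB) had a median of 0.38, against 0.23 for the other 6. That difference of 0.15 was reached by 145 of the 462 possible lists of 5 segments, so this list did not stand apart from the other mRNAs in level.

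Within the transcripts at the 3 changed junctions, the ratio of knockout over wild type varied along the RNA. In ATP8/6 the 100 nt bins had log2 ratios from -0.34 (MT, 8466 to 8565) to 1.497 (MT, 9066 to 9165), with 6 bins lower and 2 higher. Its last 30 nt had 0.851 in wild type and 5.23 in the knockout, and its profiles correlated least of all mRNAs (r = 0.175 across positions). COX3 had 1.08 in its first bin and -0.09 in its last, and its first 30 nt had 1.58 and 4.93. CYTB had 1.39 in its first bin and 0.70 in its last. COX1 was lower in all 15 bins, from -0.27 in the first to -0.87 (MT, 7102 to 7201), although its first 30 nt were slightly higher in the knockout (log2 0.08). ND5, which ends at a junction without a tRNA, lay between 0.18 and 0.80 in its 18 bins, a range of 0.61 that was close to the 0.60 of COX1. The ranges of the other 6 mRNA segments ran from 0.14 in COX2 to 0.39 in ND4L/4. Over all 11 mRNA segments, the first 30 nt differed from the rest by a median log2 of -0.04 and the last 30 nt by -0.05. These medians hide wide spreads. For the first 30 nt, values ran from -0.35 in ND5 to 1.34 in COX3, with 1.10 in CYTB and 0.67 in COX1. For the last 30 nt, they ran from -0.42 in CYTB to 2.49 in ATP8/6.

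**Figure D4:**
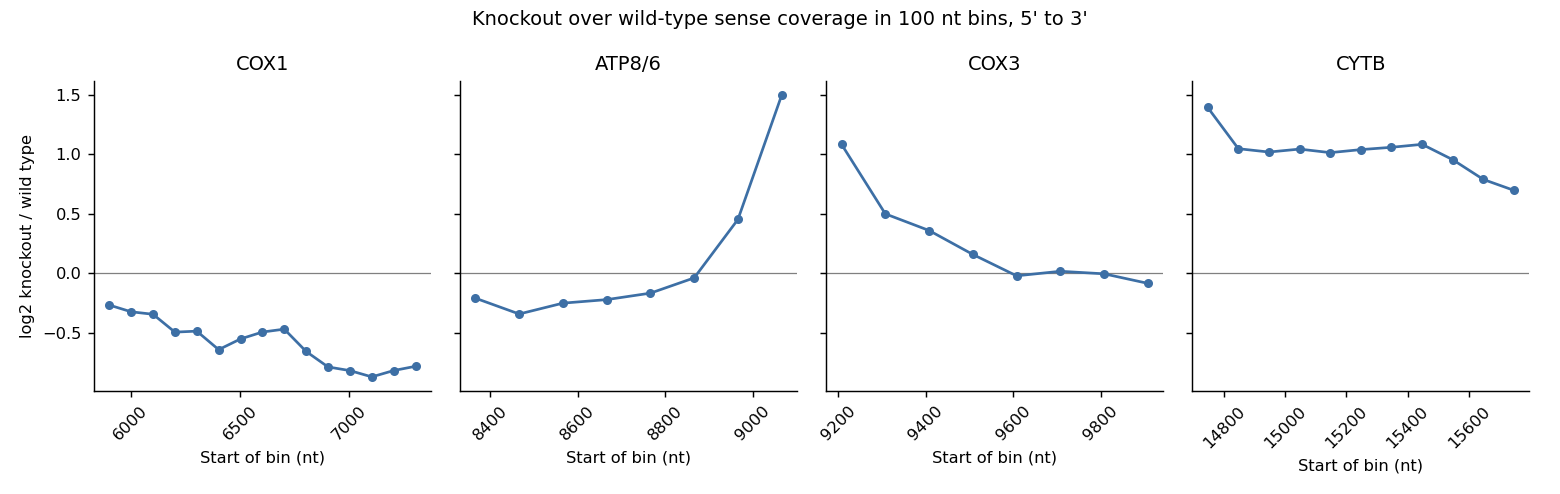
Log2 ratio of knockout over wild-type sense coverage (y axis) in bins of 100 nt against the start of each bin (nt, x axis) for COX1, ATP8/6, COX3 and CYTB, as deposited. ATP8/6 climbs to 1.497 at its 3' end and COX3 descends from 1.08, while COX1 is below 0 in all 15 bins.

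Among tRNA segments, the minus-strand cluster before COX1 was lower in the knockout tables, as was the minus-strand coverage around it. Sense coverage of tRNAY, tRNAC, tRNAN and tRNAA was 5.30, 2.65, 2.43 and 1.38 in wild type and 3.17, 1.65, 1.55 and 0.858 in the knockout, with log2 ratios from -0.74 to -0.65. Their median was below 0 under every scaling. Minus-strand coverage between tRNAY and COX1 (MT, 5892 to 5901) was 6.37 and 3.79 (log2 -0.75), and opposite tRNAW the log2 ratio was -0.74. The lower values were thus not particular to the tRNAs, and tRNA levels were not separated from coverage of longer RNAs. The other 4 minus-strand tRNAs were higher, led by tRNAP with 0.202 and 0.445 (log2 1.14), followed by tRNAS1 (log2 0.96, at means of 0.014 and 0.027), tRNAE (0.49) and tRNAQ (0.33). Under scaling by medians, quantiles or coverage outside COX1, tRNAQ lay below 0 and tRNAE lay between 0.058 and 0.13, and with a pseudocount of 0.1 tRNAS1 had 0.15. All 8 together had a median of -0.16. On either side of tRNAP, minus-strand coverage was also higher, by log2 1.19 opposite tRNAT and 0.88 at positions 16024 to 16569. Of the 14 plus-strand tRNAs, 7 had enough coverage in the sense direction, and 6 of these were higher with a median of 0.31, which lay below 0 under scaling by medians, quantiles or coverage outside COX1. The rRNAs were nearly uncovered, with RNR1 means of 0.0011 in both genotypes and RNR2 means of 0.0029 and 0.0059. Over whole classes, sense coverage averaged 2.38 and 2.40 in mRNAs, 0.600 and 0.433 in tRNAs and 0.0022 and 0.0041 in rRNAs, for wild type and knockout. The medians were 1.19 and 1.69 in mRNAs and 0.022 and 0.030 in tRNAs, so the direction for tRNAs turned between mean and median.

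Position by position, the largest differences between the genotypes lay in COX1 and ATP8/6 on both strands, and neighbouring positions are not independent. Pearson's r across positions was 0.895 on the plus strand (Spearman's rho 0.972) and 0.928 on the minus strand (rho 0.974). The 10 positions with the largest excess in the knockout on the plus strand all lay at the end of ATP6 (MT, 9195 to 9206), with 0.651 to 0.781 in wild type and 5.13 to 5.25 in the knockout. The 10 with the largest deficit all lay in COX1 (MT, 7095 to 7109), with 14.0 to 14.1 in wild type and 7.75 to 7.87 in the knockout. On the minus strand the largest excess was again within ATP8/6 (MT, 9072 to 9081), where values were 0.181 to 0.188 and 1.15 to 1.21. The largest deficit was at the start of COX1 (MT, 5935 to 5948), with 6.70 to 6.82 and 3.96 to 4.02. Plus-strand values were higher in the knockout by more than 0.2 at 5181 positions and lower at 2140, and scaling by table medians gave 3062 and 4051. On the minus strand these counts were 3507 and 1352 as deposited, and 576 and 1723 when scaled by table medians.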

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

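Scaling by unsigned coverage, scaling by coverage outside COX1, the moved junctions, the counts of stretches and of antisense segments, the single tRNAs S1, E and Q, and the sets without the ND6 3' end or COX1 were chosen after the values had been seen. Over 18 settings and 62 results there were 478 comparisons, of which 162 returned the identical value and say nothing about stability, 53 of them under scalings by a single factor. Of the other 316, 237 kept their direction and stayed within 1.5-fold (0.1 for a correlation). A log2 ratio that was itself under 1.5-fold could shrink to near 0 and still be counted as kept. ND2 did so, from 0.40 to 0.028 when scaled by table medians. For such ratios the count speaks to direction and hardly to size. No paired analysis was possible because the deposited tables carry no replicate columns, and no replicate could be left out for the same reason. Settings that need the sequence (A only, C only, G and U, fold parameters, modified sites) were not run, nor were other minimum lengths, which every mRNA segment exceeds. The outside share stayed higher in the knockout under every setting at COX1 (log2 2.54 to 3.27), ATP6/COX3 (0.92 to 1.05) and ND5/CYTB (1.02 to 3.27). With quantile normalization, ATP6/COX3 at 0.92 lay close to the tRNA-flanked ND3 5' end at 0.88. Depth is unknown, so its limit on low values could not be stated.

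Scaling by table medians gave 3062 plus-strand positions higher and 4051 lower, 576 minus-strand positions higher and 1723 lower, 5 mRNA segments higher and a median mRNA log2 of -0.16. The log2 ratios that turned were ND1 -0.18, ATP8/6 -0.17, ND6 -0.16, plus-strand tRNAs -0.058, complex I -0.17, LRPPRC-SLIRP clients -0.079 and tRNAQ -0.10. Quantile normalization gave 3435 plus-strand positions higher and 4039 lower, 1333 minus-strand positions higher and 1344 lower, 4 mRNA segments higher and a median of -0.061. It turned ND1 to -0.26, ND2 to -0.025, ATP8/6 to -0.061, ND6 to -0.14, plus-strand tRNAs to -0.38, complex I to -0.20 and LRPPRC-SLIRP clients to -0.043 and tRNAQ to -0.31, and moved ND3 to -0.81. Scaling by coverage outside COX1 gave 2912 and 4157 plus-strand positions, 753 minus-strand positions higher and 1591 lower, 4 mRNA segments higher and a median of -0.12. There ND1 was -0.20, ATP8/6 -0.19, COX3 and complex IV -0.013, ND6 -0.12, plus-strand tRNAs -0.083, complex I -0.16, LRPPRC-SLIRP clients -0.10 and tRNAQ -0.059. These scalings divide all positions of a strand by 1 factor, or reorder none, and so moved levels. The single-factor scalings left the outside shares as they were.

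With 0.01 added, the ND5 5' end turned to -0.028. With 0.1 added, the ND5/CYTB junction had 1.02, the ND2 and ND5 5' ends turned to -0.056 and -0.12, and 5 of the 330 splits were as large. A pseudocount pulls low coverage together, and log2 values were averaged in these settings. The parts of both changes in these shifts were not told apart. Junctions moved to the wild-type step gave 8 such splits, for which the cause was not tested, and leaving out the ND6 3' end gave a class difference of 2.38 with 4 of 120 splits. A difference above 0.1 gave 6132 minus-strand positions higher. A difference above 0.5 gave 3449 higher and 1622 lower on the plus strand, and 907 higher and 1088 lower on the minus strand, where the balance turned. Medians in place of means were 0.0010 and 0.0020 for rRNAs, 0.022 and 0.030 for tRNAs, and 1.19 and 1.69 for mRNAs, since a median gives high positions less weight.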

Other observations

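Coverage opposite the mRNAs was also higher in the knockout tables as deposited, except at COX1. Antisense coverage was higher opposite each of the 10 mRNA segments other than COX1, with a median log2 of 0.50 as deposited. Scaled by table medians or by coverage outside COX1, 6 of 10 were higher, and with quantiles 5 were, and the median stayed above 0, with a lowest value of 0.03. As deposited, ND6 had the largest antisense ratio (log2 1.13), followed by ATP8/6 (0.64), CYTB (0.59) and ND5 (0.57), and COX1 had -0.40. The ND6 value is the plus-strand coverage between ND5 and CYTB already described, and no separate observation, whereas the others are minus-strand coverage. On the minus strand, 4 stretches had at least 2-fold higher knockout coverage as deposited, and none had 2-fold lower coverage. Under those 3 scalings there were 2 higher stretches, at the end of COX1 and in ATP6, and 1 lower one that began in tRNAW. The 4 as deposited lay at the end of COX1 (MT, 7098 to 7398, 0.122 and 0.545), in ATP6 (MT, 8967 to 9201, 0.350 and 1.10), in ND5 (MT, 13448 to 13528, 0.092 and 0.227) and from tRNAT into the control region (MT, 15891 to 16160, 0.221 and 0.479). Across the 11 segments, antisense and sense ratios had a Pearson r of 0.578 and a Spearman rho of 0.418, and genes are not independent replicates.

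Small single-position dips of coverage recurred at the same places in both genotypes. On the plus strand 12 positions in wild type and 17 in the knockout lay more than 10% below the local median, and 12 were shared. The minus strand had 26 and 31, with 25 shared. Among the deepest were position 7663 in COX2, at -21.2% in wild type and -36.4% in the knockout, position 8255 in COX2, at -28.1% and -29.3%, and position 14803 in CYTB on the minus strand, at -27.3% and -27.8%. RNR2, otherwise nearly uncovered, had its highest knockout value of 0.147 at position 2448, where wild type had 0.067.

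Of the tests in the next 3 paragraphs, the COX1 scaling tests alone were set before their result was seen, when the segment means as deposited were already known. The junction tests and the strand tests were chosen afterwards. A first junction test used the class difference of 1.41 over all 4 sites. It was replaced once the ND6 3' end, which had no wild-type step to lose, was seen not to differ. A first test of leftover DNA used the start of the genome and was replaced, because its values of exactly 0 do not exclude a filter.

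The first pattern was the higher knockout coverage just outside COX1, ATP6/COX3 and ND5/CYTB. A difference of scaling or depth between the tables would raise tRNA-flanked junctions alike. Yet the lowest log2 ratio outside the 3 sites exceeded the highest outside the 7 tRNA-flanked ends by 1.46. The SD of 0.30 among those ends is a spread between sites and not between replicates. Their wild-type outside means were as low as 0.0075, at ND4L/4. More of every precursor in the knockout would raise coverage far from a junction as much as next to it, which was examined at CYTB alone. The ratio next to CYTB exceeded that of every window in the middle of the ND6 segment by at least 3.30. Those windows were themselves higher in the knockout by log2 1.12 to 1.44, at wild-type means as low as 0.0075. No such test was made at COX1 or ATP6/COX3. A candidate explanation is that RNAs uncut at these 3 sites were more frequent without FASTKD5, which the design names as the difference between the groups. Between ND5 and CYTB, knockout coverage fell to 0.020 (MT, 14449 to 14498). Wild-type coverage was also low at those positions, at 0.0075. Whether the RNA extended upstream of CYTB was continuous from ND5 therefore could not be told from coverage. Variation between samples stays open, because no replicate values were used.

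The second pattern was lower COX1 together with higher values of most other mRNAs. COX1 held 44.9% of wild-type coverage of both strands and 30.0% in the knockout, so a lower COX1 could raise all others through a shared total, or higher others could lower COX1. Scaled by coverage outside COX1, the median log2 ratio of the other 10 mRNA segments was -0.064 in place of 0.33, and COX1 had -0.97 in place of -0.58. That scaling centres the other segments on one another and lowers COX1 further whichever of them differed, so these tests decide nothing, although limits on both values had been set beforehand. The directions cannot be told apart without a measure outside the shared total, and CYTB, COX2 and ND5 at 0.63, 0.21 and 0.15 were high only relative to the rest.

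The third pattern was minus-strand coverage across genes read from the plus strand, 23.3% of all coverage in wild type and 24.5% in the knockout. If a fixed share of reads had been written to the wrong strand, the ratio of both strands would be even, yet the lowest 300 nt ratio was at most 0.102 of the median ratio, with 2.37% against a median of 32.4% in wild type. If the same molecules had been written on both strands, dips would recur on both, yet single-position deviations correlated at r = 0.948 between genotypes on the plus strand and at most at 0.011 between strands. Leftover mitochondrial DNA would cover the genome about evenly, yet the lowest 300 nt of minus coverage, in ND5 and without a position at 0, had at most 3.43% of the median over the 10 plus-strand mRNA segments, which argues against evenly covered DNA as the whole source. True antisense RNA is a candidate explanation, an uneven strand error of the library kit stays open, and the design has no group that would test either.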
